A study of Arabidopsis thaliana with 32 samples.

How the data were processed

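The series measured messenger RNA in Arabidopsis thaliana plants that carry a tagged ribosomal protein, HF-RPL18, under the 35S promoter. Ribosomes that hold the tagged protein can be captured by affinity, and the RNA bound to them is called TRAP RNA here. Plants grew hydroponically for 6 weeks under 10 h light and 14 h dark and were then kept for 1 day in normal medium (CK) or in medium without magnesium (MgD), in which sodium sulfate replaced magnesium sulfate. Shoot and root were sampled, and total RNA and TRAP RNA were sequenced from each, per the labels' protocols.

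The deposited table of counts holds whole numbers of reads per gene, without normalization by the authors, for 27655 genes in 24 libraries. Between 71.8% and 89.7% of the low counts of a library were even, as when the mates of a read pair are counted one by one, so the spread from counting alone is larger than the count itself implies. The deposited TPM table gives length-normalized abundances that sum to the same total in each library, and its values equal counts over 1 length per gene in 23 libraries. The tools named for the reads were FastQC, Trimmomatic, STAR 2.7.6a and Subread 2.0.0, with no settings, per the submitters' processing notes. The genome build is not given in the sources used here. Gene symbols came from a RefSeq gene table of the assembly TAIR10.1, which named 27445 of the loci, and no coordinates were used. The other 210 loci comprised 88 chloroplast-encoded and 122 mitochondria-encoded genes.

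Whole reads were recovered from the TPM values and compared with the counts, with a tolerance of 0.05 of a read. In 23 libraries both tables gave the same reads. For Root Total MgD replicate 3 the TPM column came from 11727584 reads and the count column from 6147531 reads. The count column was used, and the recovered reads served as an alternative.

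The 24 libraries form 8 groups of 3, made of tissue, RNA type and treatment. The submitters' file names carry the lane label L002 for every shoot TRAP library and L001 for all others. In shoot, RNA type and lane label therefore cannot be told apart, while the root libraries share 1 label. Another 8 samples that the labels describe as removed were not analysed here. The series describes the replicates as independent, without saying whether they came from separate plants or batches, so p-values measure only the spread between these libraries, which may be technical. Library totals ranged from 6147531 to 41472378 counts. Pearson correlations of log2 CPM within a group ranged from 0.9556 to 0.9877, and the chi-square per degree of freedom between libraries of a group was at least 11. No library was thus a copy of another in its group, and libraries of different groups were not compared in this way.

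Each comparison was tested with the edgeR 4.0.16 quasi-likelihood F test (robust glmQLFit and glmQLFTest, in R 4.3.3) after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 12 libraries of a tissue shared one model for comparisons within it, and all 24 shared one model for differences between tissues. Translational efficiency was tested as the interaction of RNA type and treatment in the count model. The design, the rule for named genes and 29 gene lists with 517 entries were chosen before the data were examined. Named genes are the 12 largest rises and 12 largest falls among called genes with a symbol, an average log2 CPM of at least 1 and, for 2 groups, no overlap between the 3 libraries of each, which chance gives for 10% of genes. For interactions and differences between tissues the number was 6 per direction. RPL18B and the magnesium transport list, for comparisons of 2 groups, and up to 4 members of each list described, those with the smallest adjusted p, were added. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. Adjustment over a list alone covers the measured members of that list in a single comparison. It does not correct across the 29 lists or across comparisons, so some members may pass it by chance. Lists of root markers, photosynthesis genes, guard cell genes and phloem genes were followed as markers of other tissues or cell types. CPM values beside named genes are TMM-scaled unless stated, and a gene at 0 in a whole group is compared with a floor of 3 counts over the group, which covers counting error only. This floor takes counts as independent. Where mates are counted one by one it is too low, and the fold bounds are too high.

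Simulated counts with known changes were tested with the same steps, on 100 genes per fold for each comparison of 2 groups. At 4-fold, 89% were recovered for root total RNA and 95% for root TRAP RNA on 19982 genes, and 97% and 96% for shoot total and shoot TRAP RNA on 19182 genes. At 2-fold the shares were 41%, 43%, 73% and 81%. These recoveries describe the simulated counts only. The real libraries had deviations from their group means in common, as described next. Whether the recoveries hold for the real comparisons was not tested, so they do not give the power behind a count of 0 genes.

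Whether replicate numbers pair the libraries was checked by the correlation of deviations from the group means over genes with a mean log2 CPM over 1. The submitters' library table gives an original number from 1 to 4 for each library, which differs from the replicate number in the labels. In the shoot, all 13 pairs with the same original number correlated above 0.1, with a lowest r of 0.114 and a mean of 0.287. Other pairs had a mean of -0.0916. Deviations within a group sum to 0, so a positive mean of same-number pairs makes that of other pairs negative. The mean of other pairs is thus no baseline. As every same-number pair passed 0.1, these numbers were taken to pair the shoot libraries. Over genes with a mean log2 CPM over 0, 12 of the 13 passed, with a lowest r of 0.0973, so the pairing rule was met only at the first minimum. In the root 10 of 13 pairs passed. By replicate number 14 of 18 root pairs passed, with a mean r of 0.295 against -0.145 for other pairs. Each of the 12 root libraries correlated best with its own replicate number. The rule was not met, so the root models leave this shared deviation out. By mean r it was as large as the shoot pairing by original number, where 10 of 12 libraries correlated best with their own number. The root p-values therefore ignore a structure that the data show. The shoot pairing by original number was found after the data were seen. The alternatives were DESeq2 1.42.0 (Wald test), its size factors, no count filter, the replicate number as a block, other sets of libraries in the model, limma on log2 TPM with pseudocounts of 1 and 0.1, a 2-fold minimum, and each library left out in turn. Added after the data were seen were the original number as a block, halved counts, the recovered reads, a fit without organelle genes and RPL18B, and a fit without the root libraries of original number 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.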

Results

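The data describe 24 libraries from Arabidopsis shoots and roots, 3 in each of 8 groups, given by tissue, total or TRAP RNA, and normal medium (CK) or 1 day without magnesium (MgD). Library totals ranged from 6147531 counts in a root total MgD library to 41472378 in a shoot TRAP MgD library. The first principal component separated shoot from root and held 78.9% of the variance, and the second separated TRAP from total RNA and held 10.7%.

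**Figure D1:**
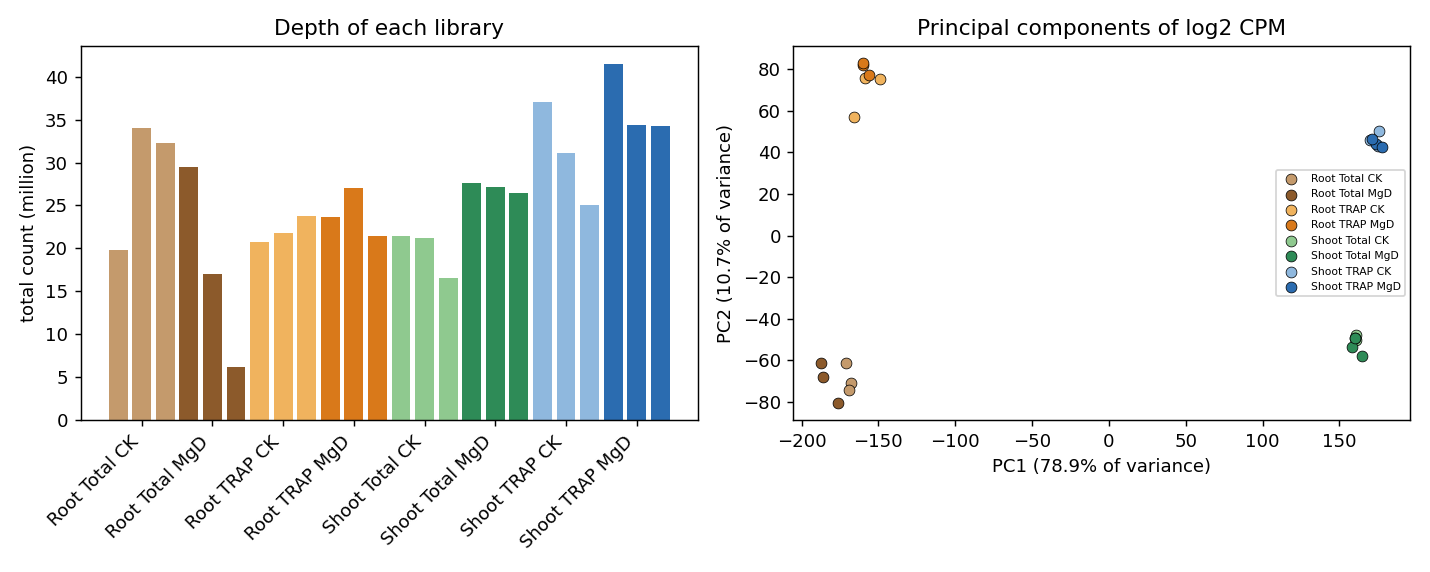
Left, total count of each library, 3 bars per group; right, the libraries on the first and second principal components of log2 CPM, coloured by group. The lowest bar, a root total MgD library, stands at 6147531 counts, and the axes carry 78.9% and 10.7% of the variance.

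TRAP RNA was compared with total RNA under CK to ask which transcripts the tagged ribosomes hold in each tissue. In roots, 15 of 16 measured flavonoid and phenylpropanoid genes were higher in TRAP RNA and 1, FLS1, was lower, and the root hair genes RHD6, RHS19 and EXPA7 were lower. Camera called this list (adjusted p 0.000596), and gave an adjusted p of 0.587 with an estimated correlation. MYB82, a MYB regulator, was 12.8-fold higher (log2 fold change 3.68 ± 0.46 SE, n = 3 and 3). TT7, a flavonoid hydroxylase, was 10.4-fold higher (3.38 ± 0.64), and HAI2, a phosphatase of abscisic acid signalling, 9.89-fold (3.31 ± 0.51). VSP2, a storage protein induced by jasmonate, rose from 61.6 ± 21 to 581 ± 230 CPM (3.24 ± 0.40), and XTH7, a cell wall enzyme, from 113 ± 11 to 981 ± 360 CPM (3.12 ± 0.24). The lipid transfer protein AZI1 (3.21 ± 0.57), the lipocalin TIL (3.40 ± 0.43) and the aquaporin PIP2E (3.09 ± 0.51) were also among the largest rises. RHD6, a regulator of root hair identity, fell from 7.70 ± 1.6 CPM in total RNA to 0.0677 ± 0.059 in TRAP RNA (SD, n = 3). Its log2 fold change was -6.65 ± 0.47, with 4 counts in the TRAP group. RHS19, another root hair gene, had -6.06 ± 0.80, and the root hair expansin EXPA7 had -6.22 ± 0.90, also with 4 counts in the TRAP group. The cellulase GH9C1 (-5.71 ± 0.80, 4 counts) and the expansin EXPA11 (-5.60 ± 0.73) were lower as well. A fall that rests on 4 counts is uncertain in size, more so where mates were counted one by one. ATGSTF13 had 0 counts in the TRAP libraries and 10.9 ± 0.65 unscaled CPM in total RNA. It was 241-fold lower against the floor, a bound that is too high where mates were counted one by one.

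Of 20311 genes tested in root, edgeR with Benjamini-Hochberg adjustment called 9785, 4597 higher and 5188 lower in TRAP RNA, and 5597 of them differed at least 2-fold, 2190 higher and 3407 lower. The counts of flavonoid and phenylpropanoid genes, 15 higher and 1 lower, were the same over all genes and adjusted over the list alone, among them UF3GT (3.36 ± 0.49) and TT5 (1.84 ± 0.27), with the flavonol synthase FLS1 lower (-2.73 ± 0.46). Of 6 phloem genes, 5 were higher over all genes and 6 adjusted over the list alone, led by FTIP1 (2.11 ± 0.18) and SUC2, the phloem sucrose transporter (1.28 ± 0.15). Their camera adjusted p was 0.00203, and 0.509 with an estimated correlation. Of 17 glucosinolate genes 12 were higher and 2 lower, 13 and 2 adjusted over the list alone, with a camera adjusted p of 0.00939, and 0.587 with an estimated correlation. Among 40 photosynthesis genes, 26 were higher and 4 lower, 27 and 4 adjusted over the list alone, including LHCB1.5 (2.80 ± 0.40) and RBCS2B (-4.37 ± 0.67). For this list the camera adjusted p was 0.00112, and 0.646 with an estimated correlation. Of 10 root markers, 1 was higher and 6 lower over all genes and adjusted over the list alone, including CASP1 of the endodermis (-2.76 ± 0.20) and RHD2, the root hair oxidase (-1.57 ± 0.17). Camera did not call this list (adjusted p 0.0669). On TPM values without TMM scaling the median of all genes moved by -0.475 on the log2 scale. Limma then called 1889 higher and 9202 lower, so directions in root are relative to the median of all genes.

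RPL18B, whose protein is the tagged one, rose in TRAP RNA 7.07-fold in root (2.82 ± 0.27) and 15.4-fold in shoot (3.95 ± 0.12), from 1950 ± 150 to 30100 ± 3100 CPM in shoot (SD, n = 3). In shoots, 15 of 17 measured genes of glucosinolate synthesis, the defence compounds of this plant family, were higher and 1 was lower. Camera called them as a list (adjusted p 9.28e-08), and gave an adjusted p of 0.329 with an estimated correlation. BCAT4, an enzyme that starts the chain extension of methionine, was 4.11-fold higher (2.04 ± 0.21). IPMI2 of the same pathway was 4.08-fold higher (2.03 ± 0.20), GSTU20, a glutathione transferase, 6.06-fold (2.60 ± 0.18), and GolS2, an enzyme of raffinose synthesis, 5.52-fold (2.46 ± 0.34). FTIP1, a companion cell protein that moves the florigen FT, was 9.03-fold higher (3.17 ± 0.13). SDD1, a protease of stomatal patterning, fell to 0.167 ± 0.16 CPM from 5.84 ± 1.3 (-5.01 ± 0.74), and TGG2, a myrosinase, fell from 778 ± 110 to 95.8 ± 6.4 CPM (-3.02 ± 0.16). The phosphate transporter PHT1;1 (-4.87 ± 0.62), the proline-rich protein PRP2 (-3.41 ± 0.15) and the pathogen-induced PCC1 (-2.98 ± 0.22) were lower as well.

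Of 19341 genes tested in shoot, edgeR called 8678, 4118 higher and 4560 lower, and 2916 of them differed at least 2-fold, 743 higher and 2173 lower. The lane label also differs between shoot TRAP and shoot total libraries, so its share in these differences cannot be told apart. The counts of glucosinolate genes, 15 higher and 1 lower, were the same over all genes and adjusted over the list alone, with CYP79B2 (1.93 ± 0.15) and CYP83A1 (1.77 ± 0.13) among them. Of 10 aquaporins, 9 were higher and 1 lower over all genes and adjusted over the list alone, including TIP2;2 (1.38 ± 0.14). The aquaporin list had a camera adjusted p of 0.00348, and 0.618 with an estimated correlation. Of 23 ethylene genes 11 were higher and 0 lower over all genes and adjusted over the list alone, with a camera adjusted p of 0.00348, and 0.431 with an estimated correlation. All 4 called members of 6 guard cell genes were lower, also adjusted over the list alone, with FAMA, a stomatal regulator, at -2.43 ± 0.20 and MYB60 at -1.81 ± 0.28. The guard cell list had a camera adjusted p of 0.0357, and 0.329 with an estimated correlation. Of 10 genes with conserved upstream open reading frames, which are known to limit translation, 6 were lower over all genes and adjusted over the list alone, such as BZIP11 (-1.08 ± 0.18). Their camera adjusted p was 0.0445, and 0.329 with an estimated correlation. Chloroplast-encoded transcripts took 4.69% ± 0.63 of the counts in shoot total RNA and 0.00594% ± 0.0019 in shoot TRAP RNA (SD, n = 3).

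Magnesium transporters differed between the RNA types in part. Of 11 measured in root, MGT8 (-2.68 ± 0.39), CNGC10 (-1.68 ± 0.33) and MGT7 (-1.08 ± 0.29) were lower in TRAP RNA, and MGT10 (0.68 ± 0.20) and MGT4 (0.36 ± 0.11) higher, 2 higher and 4 lower adjusted over the list alone; MGT4 had the other sign on unscaled TPM. Of 10 in shoot, MGT4 was higher (0.78 ± 0.11) and MGT6 lower (-0.55 ± 0.11), over all genes and adjusted over the list alone.

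**Figure D2:**
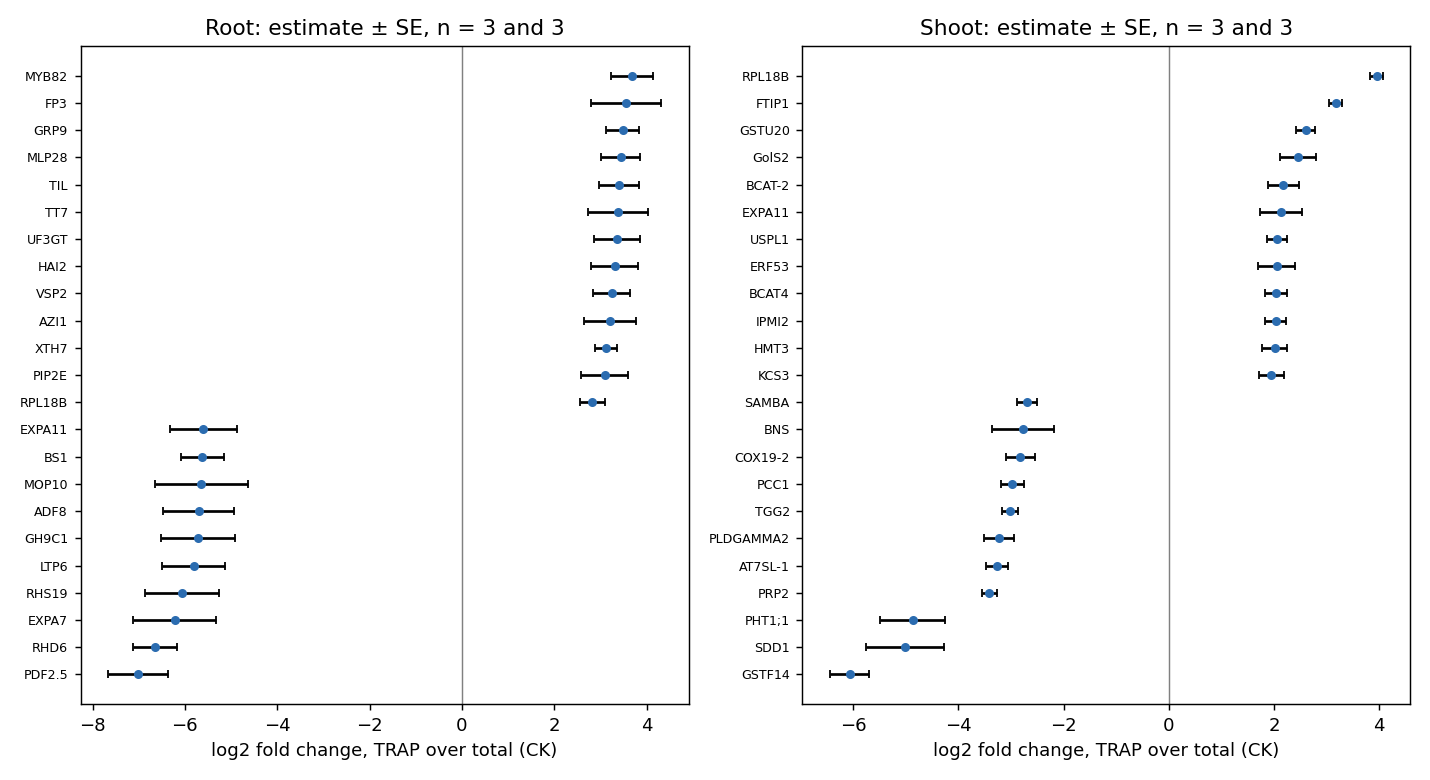
Log2 fold change of TRAP over total RNA under CK with its SE (n = 3 and 3) for the named genes of root, left, and shoot, right; genes with 3 or fewer counts in the TRAP group are left out. RPL18B stands at 2.82 in root and 3.95 in shoot, and RHD6 at -6.65 in root, which rests on 4 counts in the TRAP group.

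The response of shoots to MgD was asked in total RNA and in TRAP RNA. CAX1, a vacuolar exchanger of calcium and protons, had 300 ± 64 unscaled CPM in total RNA under CK and 560 ± 88 under MgD (SD, n = 3). In TRAP RNA it had 255 ± 53 and 585 ± 72. All 3 MgD libraries lay above all 3 CK libraries in both RNA types. In a single comparison chance separates the groups, in either direction, for 10% of genes. Its log2 fold change was 0.84 ± 0.18 in total RNA and 1.19 ± 0.18 in TRAP RNA. It was higher when adjusted over the cation and calcium list alone (edgeR, Benjamini-Hochberg adjusted p 0.00841 and 0.000321). Over all genes its edgeR adjusted p was 1 and 0.27. CBL2, a calcium sensor, was the other of 23 measured members to pass in TRAP RNA, at 0.39 ± 0.11 adjusted over the list alone, and did not pass with the original library number as a block (0.32, list-alone adjusted p 0.0678). With that block, which pairs the shoot libraries, CAX1 passed over all genes at 0.85 in total RNA (adjusted p 0.00695) and 1.04 in TRAP RNA (adjusted p 0.00036). NUDT5, a nudix hydrolase named after its values were seen, passed with it in TRAP RNA at 1.32 (adjusted p 0.00125).

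**Figure D3:**
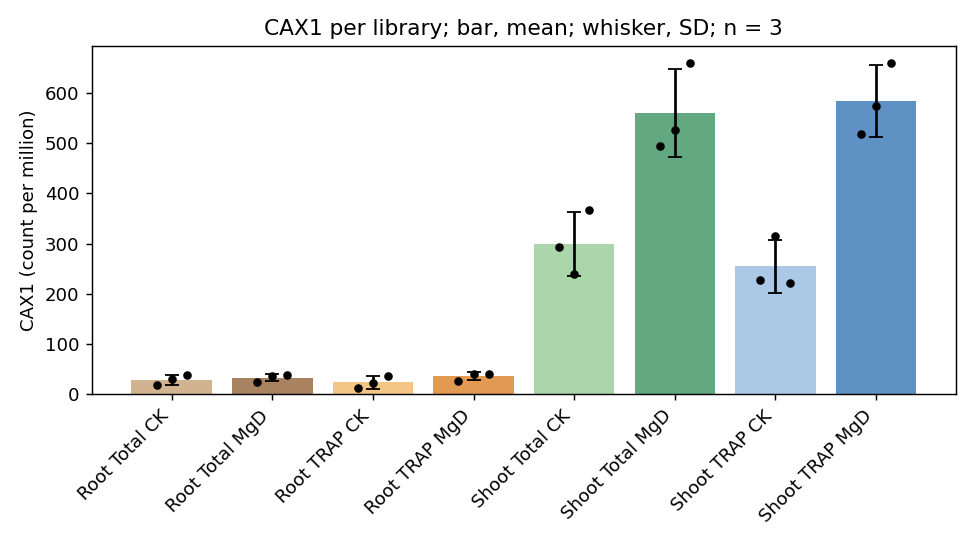
CAX1 in unscaled CPM per library; bars are means of 3 libraries, whiskers SD and points libraries. The shoot means are 300 and 560 in total RNA and 255 and 585 in TRAP RNA under CK and MgD.

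In shoot total RNA edgeR called 0 of 19341 genes. At an unadjusted p under 0.05 there were 355, where 967 would be expected if no gene changed. DESeq2 called 0 and limma 0, and with the original-number block edgeR called 1. In shoot TRAP RNA edgeR called 0, with 1433 at an unadjusted p under 0.05 against the same 967 expected. DESeq2 called 16 and limma 0, and with the original-number block edgeR called 2. Aquaporins were lower as a list in TRAP RNA (median -0.42, 0 of 10 over all genes and 3 lower adjusted over the list alone: TIP2;1 -0.44 ± 0.14, PIP1;2 -0.48 ± 0.16 and PIP1;1 -0.39 ± 0.14). The list's camera adjusted p was 3.38e-05, 0.00013 with the original-number block and 0.88 with an estimated correlation. With the block TIP2;1 passed adjusted over the list alone (-0.33, edgeR adjusted p 0.0385), and PIP1;2 (0.0549) and PIP1;1 (0.0622) did not. In total RNA the aquaporin median was -0.19, with a camera adjusted p of 0.0063, 0.000443 with the block and 0.753 with an estimated correlation. Camera called 8 lists in shoot total RNA and 5 in shoot TRAP RNA, and with the block 2 and 2, with aquaporins in both. Photosynthesis genes had a median of -0.12 in total RNA (camera adjusted p 3.47e-05, 0.0531 with the block) and of 0.12 in TRAP RNA (0.0271, 0.29 with the block), with an adjusted p of 0.753 and 0.977 with an estimated correlation. None of the 10 measured magnesium transporters passed in either RNA type, by edgeR over all genes or adjusted over the list alone; the smallest unadjusted p were 0.0942 and 0.031, both for MHX.

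The response of roots was asked in the same way. Photosynthesis genes made up 0.199% ± 0.017 of the counts in root total RNA under CK and 0.112% ± 0.037 under MgD (SD, n = 3). As a list they were lower (median -0.94), with 0 of 40 lower over all genes and 14 lower adjusted over the list alone, among them LHCA1 (-0.96 ± 0.23) and PSBQA (-1.08 ± 0.27). Camera gave an adjusted p of 3e-35, and 0.31 with an estimated correlation. In the root TRAP libraries the list took 0.385% ± 0.18 under CK and 0.372% ± 0.11 under MgD. Nuclear transcripts typical of shoots but outside photosynthesis stood at 1.4%, 1.47% and 1.55% of their shoot level in the CK root total libraries and at 0.729%, 0.759% and 1.47% in the MgD ones. They were chosen for at least 50 CPM in shoot total RNA and at least 100 times their root TRAP level. Sulfate starvation genes were higher as a list in root total RNA (median 0.86, 0 of 14 over all genes or adjusted over the list alone), led by SDI1 (1.70 ± 0.51). Their camera adjusted p was 3.5e-09, and 0.173 with an estimated correlation. In root TRAP RNA SDI1 had 49.5 ± 36 CPM under CK and 58.2 ± 24 under MgD (SD, n = 3). Aquaporins were lower as a list (median -0.29, 0 of 10 over all genes or adjusted over the list alone; camera adjusted p 1.59e-05, and 0.31 with an estimated correlation). Iron deficiency genes were higher as a list (median 0.40, 0 of 25 over all genes or adjusted over the list alone; camera adjusted p 0.000643, and 0.444 with an estimated correlation). Its members varied widely between MgD libraries: S8H, an enzyme of coumarin synthesis, had 23.3 ± 3.9 CPM under CK and 61.1 ± 55 under MgD (SD, n = 3), and its log2 fold change of 1.4 ± 0.89 was 0.07 with the original-number block.

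**Figure D4:**
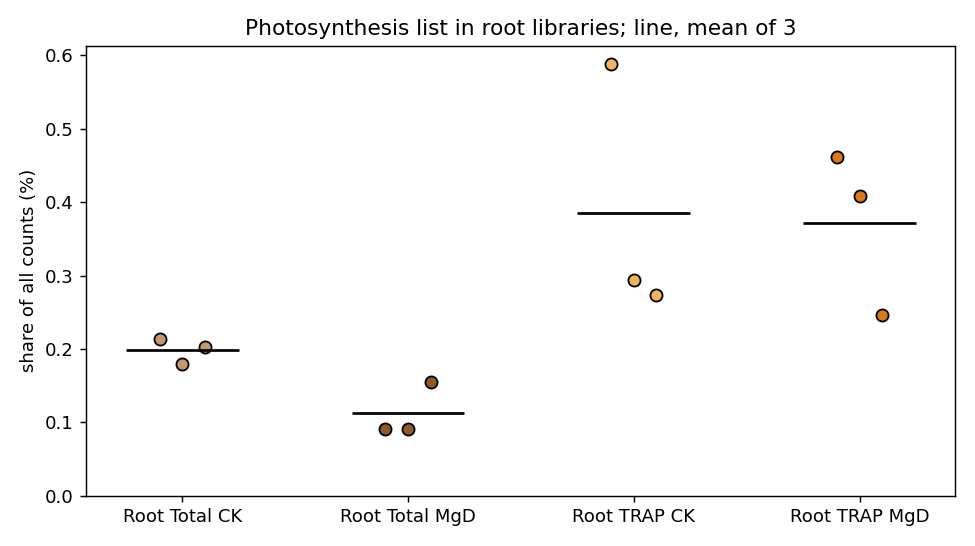
Share of all counts taken by the 40 photosynthesis genes in each root library, in percent; points are libraries and lines means of 3. The root total means are 0.199 under CK and 0.112 under MgD.

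In root TRAP RNA, phloem genes were higher as a list (median 0.40, 0 of 6 over all genes and 2 adjusted over the list alone, SUC2 at 0.62 ± 0.15 and FTIP1 at 0.60 ± 0.17). Their camera adjusted p was 0.00566, and 0.249 with an estimated correlation. CAX3, a vacuolar exchanger related to CAX1, was higher adjusted over the list alone (1.04 ± 0.26). Of 10 genes with conserved upstream open reading frames, 3 were lower adjusted over the list alone, SAC51 (-0.72 ± 0.19), HSFB1 (-1.11 ± 0.29) and BZIP2 (-0.68 ± 0.19), and 0 over all genes; the camera adjusted p was 0.254. RD29A (-0.84 ± 0.23) and ABI2 (-0.95 ± 0.27), genes of the abscisic acid response, were lower adjusted over their list alone. In root total RNA edgeR called 0 of 20311 genes. At an unadjusted p under 0.05 there were 503, where 1016 would be expected if no gene changed. DESeq2 called 1, the aquaporin PIP1C at -0.49, and limma 1 and 0 with the pseudocounts of 1 and 0.1. With all 24 libraries in one model edgeR called 7 in root total RNA and 133 in root TRAP RNA. In root TRAP RNA edgeR called 0, with 2284 at an unadjusted p under 0.05 against the same 1016 expected. DESeq2 called 170, 54 higher and 116 lower, and limma 0. None of the 11 measured magnesium transporters passed in either root RNA type by edgeR, over all genes or adjusted over the list alone; the smallest unadjusted p were 0.146 and 0.107.

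Whether MgD moved TRAP RNA and total RNA by different amounts, the response of translational efficiency, was tested as an interaction. In root, SUC2 passed adjusted over the phloem list alone (0.81 ± 0.21). SAC51 (-0.86 ± 0.26), HSFB1 (-1.23 ± 0.41) and VTC2, an enzyme of ascorbate synthesis (0.63 ± 0.20), passed adjusted over the list of conserved upstream open reading frames alone. Adjusted over all genes, SUC2, SAC51, HSFB1 and VTC2 each had an edgeR adjusted p of 0.934. In shoot, IAA29, an auxin response gene, passed adjusted over its list alone (1.63 ± 0.42, edgeR adjusted p 0.00853), and also with the block (1.04, adjusted p 0.0256). Over all genes edgeR called 0 in root, with 968 at an unadjusted p under 0.05, where 1016 would be expected if no response differed. In shoot it called 0, with 764 against 967 expected. DESeq2 called 5 in root and 0 in shoot, and limma 0 and 0. With the original-number block edgeR called 0 in shoot. With that block set within treatment it called 3, of which DR4, a protease inhibitor family member named after its values were seen, had 0.79. As a list, photosynthesis genes had an interaction median of 0.75 in root, with 0 of 40 over all genes or adjusted over the list alone (camera adjusted p 2.24e-12, and 0.642 with an estimated correlation). In root total RNA the shoot-typical transcripts outside photosynthesis were lower in MgD replicates 1 and 2, at 0.729% and 0.759% of their shoot level against at least 1.4% under CK, while the photosynthesis share of root TRAP RNA was 0.385% ± 0.18 under CK and 0.372% ± 0.11 under MgD. In shoot the photosynthesis median was 0.24, with 0 of 40 by either adjustment (camera adjusted p 3.22e-06, 0.0493 with the block, and 0.944 with an estimated correlation).

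The response was also compared between root and shoot. In total RNA edgeR with Benjamini-Hochberg adjustment called 5 of 21163 genes, all lower in root relative to shoot. BBX15, a B-box protein, had -1.80 ± 0.29 (adjusted p 0.0204), with 2.97 ± 0.65 unscaled CPM in root under CK and 0.989 ± 0.18 under MgD, against 270 ± 10 and 307 ± 39 in shoot (SD, n = 3). NdhN, a subunit of a chloroplast dehydrogenase complex, had -3.16 ± 0.52 (adjusted p 0.0275). MYB16, AT2G29290 and AT5G50915 had 0 counts in root under MgD. Against the floor they were 7.79-fold, 8.91-fold and 3.99-fold lower there than under CK, bounds that are too high where mates were counted one by one. MYB16 and AT5G50915 did not pass the count filter of the root libraries alone. AT2G29290 and AT5G50915 were named after their values were seen. All 5 were far higher in shoot, as NdhN with 0.562 ± 0.093 unscaled CPM in root and 61.6 ± 5.0 in shoot under CK. Shoot-typical transcripts outside photosynthesis stood at 1.4% to 1.55% of their shoot level in root total RNA under CK. They were lower in MgD replicates 1 and 2, at 0.729% and 0.759%. In MgD replicate 3 they stood at 1.47%, as under CK, while BBX15 was low across the 3 MgD libraries (0.989 ± 0.18 unscaled CPM). With the original-number block none of the 5 and 2 other genes passed, TL29 (-1.87) and AT5G45950 (-3.94), named after their values were seen, and without Root Total MgD replicate 3 the count was 22. Without Root Total MgD replicate 1, Shoot Total CK replicate 3 or Shoot Total MgD replicate 1 edgeR called 0. With halved counts 1 gene passed, BBX15, and with the reads recovered from TPM for Root Total MgD replicate 3 there were 2, AT5G50915 and CER1, the latter named after its values were seen. In TRAP RNA edgeR called 0, with 2301 at an unadjusted p under 0.05, where 1058 would be expected if no response differed. DESeq2 called 144 there, and without Root TRAP CK replicate 3 edgeR called 133. There, phloem genes were higher in root relative to shoot, with 0 of 6 over all genes and 2 adjusted over the list alone, FTIP1 (0.92 ± 0.21) and SUC2 (0.89 ± 0.19). Camera gave an adjusted p of 8.33e-05, and 0.115 with an estimated correlation. Aquaporins were also higher in root relative to shoot (median 0.58, 0 of 10 over all genes and 4 adjusted over the list alone, TIP2;1 at 1.01 ± 0.28 and PIP2;3 at 1.09 ± 0.38 among them), with a camera adjusted p of 0.000409, and 0.634 with an estimated correlation.

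Across genes, which are not independent replicates, the log2 fold changes of total and TRAP RNA correlated with r = 0.288 in root and 0.115 in shoot (Spearman 0.204 and 0.0592). Leaving out 1 library moved r to between 0.112, without Root TRAP CK replicate 1, and 0.413, without Root TRAP CK replicate 2, in root. In shoot it moved to between -0.0268, without Shoot Total MgD replicate 3, and 0.279, without Shoot Total MgD replicate 1, so its sign was not settled. Those of root and shoot correlated with r = 0.199 in total RNA and -0.0168 in TRAP RNA (Spearman 0.22 and -0.0425). These ranged from 0.0765 to 0.258, without Shoot Total MgD replicates 1 and 3 in turn, and from -0.062, without Root TRAP CK replicate 1, to 0.0137, without Shoot TRAP CK replicate 2.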

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

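The tests of the photosynthesis genes in root total RNA and the pairing of the shoot libraries by original number were chosen only after the result was seen, and the keywords that set photosynthesis genes apart were tightened after a first run.

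The response of total RNA to MgD differed between root and shoot in 5 genes, by the edgeR interaction test with Benjamini-Hochberg adjustment. The adjusted p was 0.0204 for BBX15, AT2G29290 and AT5G50915 and 0.0275 for MYB16 and NdhN. Their levels in root total RNA under CK, between 0.227 and 2.97 CPM, stood far below those in shoot, between 14.2 and 270 CPM. Shoot-typical transcripts outside photosynthesis were also lower in root total RNA in MgD replicates 1 and 2 (0.729% and 0.759% of their shoot level, against at least 1.4% under CK), and not in replicate 3 (1.47%). Of 50 splits drawn 1, the real one, called as many as 5 genes, and the highest other called 2. That is a share under 0.05, but also the smallest share 50 splits can give. The splits ignore the original number, so they do not exclude chance. At an unadjusted p under 0.05 the real split gave 581 genes, where 1058 would be expected if no response differed. At least as many came from 32 of the 50 splits, and the highest other gave 1865. With the original number as a block none of the 5 was called and 2 other genes were. Leaving out Root Total MgD replicate 1, Shoot Total CK replicate 3 or Shoot Total MgD replicate 1 gave 0 genes, and leaving out Root Total MgD replicate 3 gave 22. Halved counts gave 1, and the reads recovered from TPM for that library gave 2. The TPM column of Root Total MgD replicate 3 came from 11727584 reads that the count comparisons did not use.

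Photosynthesis transcripts were lower as a list in MgD than in CK root total RNA by camera, with an adjusted p of 3e-35, and 0.31 with an estimated correlation, and edgeR called 0 of 40 members over all genes. The tables argue against lower expression of photosynthesis genes in MgD roots as the whole cause, since 95 tested shoot-typical genes outside photosynthesis had a median log2 fold change of -0.85 (SD 0.67), with 90.5% below 0. A smaller amount of shoot RNA in the MgD root total libraries is a candidate explanation: per unit of shoot level, these genes fell by 0.887 of the fall of the photosynthesis list. It leaves Root Total MgD replicate 3 open, where these genes stood at 1.47% of their shoot level, as under CK, and the photosynthesis list at 0.989%. A change shared by photosynthesis and other shoot-typical genes in root cells stays untested. The shoot-typical genes were chosen to be scarce in root TRAP RNA, and stood there at 0.131% to 0.214% of their shoot level. The photosynthesis list stood at 1.57% to 3.74% in root TRAP RNA. The 2 sets thus differ in root, which limits what one can show about the other.

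Root hair transcripts were lower in root TRAP than in root total RNA. Gene length is too small an effect to account for it: the median log2 fold changes of length deciles spanned only -0.52 to 0.11. The 6 root markers called lower, picked for being lower and not all of root hairs, kept a median of -2.41 after their decile's median was subtracted. Low abundance does not account for the lower root hair transcripts either. The median of 12 other root hair genes lay at percentile 0.01 among 10000 sets matched on expression, the smallest these sets can give. Fewer tagged ribosomes recovered from root hair cells may contribute, as these 12 genes had a median of -4.32, or -4.1 with the 2 genes at 0 set to their floor, and 10 were called lower. Poor translation of these transcripts stays open, and root hairs leave CASP1, SCR and PIN2, markers of other root cells that were also lower, without an account.

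Shoot libraries deviated from their group means by original number. The lowest correlation among the 13 pairs with the same number, 0.114, restates this pattern and cannot test its source. A batch of growth or preparation stays an untested candidate. Different harvest times cannot be told apart from other batch effects: the mean absolute correlation of 17 clock genes with the first residual component lay at percentile 87.2 of random lists, short of both bounds set for it.

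For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split and the highest other called 0 and 0 genes for root total RNA, 0 and 3 for root TRAP RNA, 0 and 0 for shoot total RNA, 0 and 1 for shoot TRAP RNA, 9785 and 0 for root TRAP against total RNA, and 8678 and 0 for shoot. At an unadjusted p under 0.05 other splits reached 1636 genes in root total RNA against 503 and 3814 in root TRAP RNA against 2284, which points to a structure of the libraries besides treatment. In shoot they reached 1724 genes in total RNA against 355 and 2315 in TRAP RNA against 1433. Those shoot splits, and the one that reached 1636 genes in root total RNA, separated the original numbers 3 and 4 from 1 and 2. The highest root TRAP split did not, with number 2 on both sides. With that number as a block edgeR called 1 and 2 genes in shoot total and TRAP RNA, and 0 in root total RNA. For the interactions with 0 calls each of the 50 splits drawn gives as many by construction, so the splits say nothing about chance. The highest other called 2 for root and 1 for shoot translational efficiency and 6 for TRAP RNA between tissues.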

How the results depend on the processing

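The fits with the original number as a block, halved counts, reads recovered from TPM, no organelle genes and RPL18B, or no root libraries of original number 1 were chosen only after the data were seen. Adding the removed libraries was not run; they are not analysed here. Of 9477 values of named genes under alternatives, 9361 kept their side of the threshold, 77 lost the call and 37 gained one. The 9361 include 6701 uncalled values that stayed uncalled, of which 132 had the other sign. MGT4 in root TRAP against total RNA reversed to -0.127 and -0.13 with limma on TPM + 1 and + 0.1, a scale without TMM. Of 209 counts 172 stayed within 1.5 times. With a 2-fold minimum, which removes calls by construction, TRAP against total RNA gave 5597 genes in root and 2916 in shoot. For all other counts that moved, the cause was not tested.

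DESeq2 called 1 gene in root total RNA, 170 in root TRAP RNA, 16 in shoot TRAP RNA, 5 for root translational efficiency, and 14 and 144 for total and TRAP RNA between tissues. Limma on TPM + 1 called 1 in root total RNA. All 24 libraries in one model gave 7 in root total and 133 in root TRAP RNA. The replicate block gave 64 genes in shoot TRAP RNA, 6 for shoot translational efficiency (2 within treatment) and 3 for total RNA between tissues. In root, every library correlated best with its own replicate number, with a mean r of 0.295 against -0.145 for other pairs, which is negative by construction. As only 14 of 18 pairs passed 0.1, these numbers were not taken to pair them. The main root comparisons therefore do not account for this structure. The original-number block gave 1 in shoot total RNA, 2 in shoot TRAP RNA, 3 for shoot translational efficiency within treatment and 2 for total RNA between tissues, and moved no other count of genes by over 1.5 times. For total RNA between tissues, halved counts gave 1, reads recovered from TPM 2, and leaving out the root libraries of original number 1 gave 0, and 2 for TRAP RNA.

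Leaving out 1 library gave 0 to 1 genes in shoot TRAP RNA (1 without CK 2 or CK 3) and 0 to 1 for shoot translational efficiency (1 without TRAP CK 3). It gave 0 to 22 for total RNA between tissues (22 without Root MgD 3; 0 without Root MgD 1, Shoot CK 3 or Shoot MgD 1; 1 without Root CK 1, Shoot CK 1 or Shoot CK 2; 2 without Root CK 3 or Shoot MgD 3). It gave 0 to 133 for TRAP RNA between tissues (133 without Root CK 3, 4 without Root CK 2). TRAP against total RNA gave 7792 to 9983 calls in root and 7438 to 8581 in shoot. Lists called by camera fell to 0 in all 10 comparisons with an estimated correlation, to 2 with the replicate block in root TRAP RNA, and were 2, 2, 2 and 5 with the original-number block in shoot total RNA, shoot TRAP RNA, shoot translational efficiency and TRAP RNA between tissues. Correlations across genes ranged from 0.112 to 0.413 for root total and TRAP RNA, -0.0268 to 0.279 for shoot, 0.0765 to 0.258 for total RNA of root and shoot (0.131 with the original-number block) and -0.062 to 0.0137 for TRAP RNA. At 2-fold, simulated recovery was 13% for root and 54% for shoot translational efficiency.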

Other observations

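In shoot TRAP RNA, CHE, a clock regulator, was higher under MgD adjusted over the clock list alone (0.44 ± 0.11, edgeR Benjamini-Hochberg adjusted p 0.0278, and 0.0473 with the original-number block). In root TRAP RNA the clock gene RVE4 was higher adjusted over that list alone (0.61 ± 0.14, adjusted p 0.0184, and 0.0543 with the block). Heat shock genes were lower as a list in root TRAP RNA (median -0.51, 0 of 10 over all genes or adjusted over the list alone), with a camera adjusted p of 0.00861, and 0.249 with an estimated correlation. Starch and sucrose genes were higher in root TRAP than in root total RNA under CK, 12 of 25 over all genes and adjusted over the list alone, with a camera adjusted p of 0.0081, and 0.587 with an estimated correlation.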
